A study of Drosophila melanogaster with 6 samples.

How the data were processed

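Total RNA of 6 embryo batches was measured on 6 Affymetrix arrays, 3 per group, with 1 batch per array. Per the labels' protocols, RNA was extracted with RNeasy columns and DNase I, labelled by the One-Cycle procedure and hybridised to GeneChip Drosophila Genome 2.0 arrays, and unfertilised eggs were left out. The authors processed the scans with GCOS, per the submitters' processing notes; its version is not given in the sources used here. The deposited signal is an intensity on a linear scale, and the trimmed mean, leaving out 2% per end, was 500 on each array, which shows a global scaling by the authors. Both deposited tables hold identical signals. Per the file headers, 1 of them also holds the authors' detection call per array and, per pair, a log2 ratio, a change call and a change p-value, which is small for an increase and near 1 for a decrease. For arrays, their number limits the precision. The design text states independent RNA samples.

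Control probe sets (183) were left out of 18952, and 18769 stayed. Of these, 13646 had 1 gene symbol, 402 had several and 4721 had none, and no gene was named from a probe set with several. The Entrez number of 13543 was found in a gene table of assembly Release 6 plus ISO1 MT, used for names, chromosome and gene order only. Of 479 entries in 33 gene lists, 474 had a current symbol and 355 a probe set of their own.

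Signals were used as log2(signal + 16), without further normalization, so that folds are on this scale and understate the change of dim probe sets. Probe sets with a present call on at least 3 of 6 arrays were kept (10137). The test was limma 3.58.1 in R 4.3.3, with lmFit and eBayes with an intensity trend, two-sided, with the replicate number as a block and Benjamini-Hochberg adjustment at 0.05. The fit had 2 residual and 3.56 prior degrees of freedom. Where a probe set was absent on all arrays of a group, a bound is given: the mean log2 value of the other group against, per array, the higher of its own value and the lowest signal with a present call. Gene lists were tested with camera at a preset correlation of 0.01, over 1 probe set per gene, the one with the highest mean, for lists with at least 3 measured members. Adjustments of members over their list alone were not corrected over the number of lists. Fisher tests, bootstraps and 10000 random lists were computed with Python 3.11.15, scipy 1.17.1, pandas 2.3.3 and numpy 2.4.6.

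The design text calls the experiments paired in 3 replicates, and the authors' ratios set arrays of the same number against each other, so the block was kept. The deviations of same-numbered arrays from their group means correlated at 0.437, 0.385 and -0.190 for pairs 1, 2 and 3, across probe sets, and arrays of different numbers at up to 0.422 (6xbcd replicate 2 with 2xbcd replicate 3). The values thus do not single out the numbered pairs, and the block rests on the design text.

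On simulated data of the 10137 probe sets, in 5 runs, the fit recovered 74.8% of log2 changes of 1 and 99% of changes of 2, with a false share of 6.36% among calls. In simulated lists, a list shifted by 0.5 was called in 5 of 5 runs, and 0 other lists were called. The simulated noise was drawn independently for each probe set from the variances of the fit. These shares thus describe the fitted model, and do not cover probe sets that vary together or an array that stands apart.

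The test, the lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule names bcd, Mabi, the 12 named probe sets with the largest change in each direction among those past the threshold with 1 sign in all pairs, and of each list up to 4 members with the smallest p. Of these list members the text prints those with the smallest p in each list, and the others were run through every alternative too. PPO1, PPO2, Bhmt, Shmt and pug lie outside the rule and were chosen after their values were seen. The alternatives were no block, quantile or median scaling, offsets of 1 and 64, no filter or a present call on all 6 arrays, no trend, a threshold of 0.1, the other table, each pair or array left out, and for lists also an estimated correlation, fry and the mean of all probe sets. Autosomal probe sets alone, lists without X-linked genes and the main axis of the arrays as a covariate were added after seeing the data.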

Results

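RNA was measured in 6 batches of Drosophila melanogaster embryos, 3 from mothers carrying 6 copies of bicoid (6xbcd) and 3 from mothers carrying 2 copies (2xbcd). Bicoid (bcd) is the maternal transcription factor that patterns the head and thorax, and its RNA is placed at the anterior of the egg by the mother. Males of the TT16 line were crossed to TT16 females for 2xbcd and to bcd+t8 females for 6xbcd, so that the mothers' stock and their bcd copies changed together. Each array of the Drosophila Genome 2.0 type carried RNA of over 100 eggs, collected for 90 min and kept for 8 h at 25 degrees, when embryos are at stages 12 to 13. Between 9751 and 10527 probe sets per array had a present call, and 10137 probe sets were tested. By these crosses the embryos' own genotype differed between the groups as well. The comparison asks which transcripts of the embryo differ when the mother carries extra bcd. It cannot part her bcd copies from her stock or from the embryos' genotype.

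The bcd transcript was higher in embryos of 6xbcd mothers. Its signal was 1736 ± 523 (SD, n = 3) in 6xbcd and 569 ± 281 (SD, n = 3) in 2xbcd embryos, a 3.16-fold difference, with a log2 change of 1.66 and a standard error of 0.154 (limma adjusted p = 0.0189). The 6xbcd arrays read 2335, 1497 and 1375 and the 2xbcd arrays 861, 546 and 301, in the order of the replicate number, and bcd was higher in 3 of 3 pairs. Without the replicate pairing the log2 change was the same and the adjusted p was 0.118, so this call depends on the pairs. It was also lost without replicate 1 (adjusted p = 0.0760), without replicate 2 (0.0984) and without the intensity trend (0.140). Ama, a neighbour of bcd on chromosome 3R that encodes a secreted immunoglobulin-like protein, had a log2 change of -0.02 (adjusted p = 0.952).

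Mabi, a cell death gene on 2L, had a signal of 128 ± 25.4 (SD, n = 3) in 6xbcd and 34.3 ± 3.65 (SD, n = 3) in 2xbcd embryos. Its log2 change was 1.5 with a standard error of 0.226, and it was higher in 3 of 3 pairs. With the pairs as a block its limma adjusted p was 0.0532, and without them 0.0262. In the authors' deposited table Mabi had an increase call in all 3 pairs, with log2 ratios of 1.2, 2 and 2.1.

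**Figure D1:**
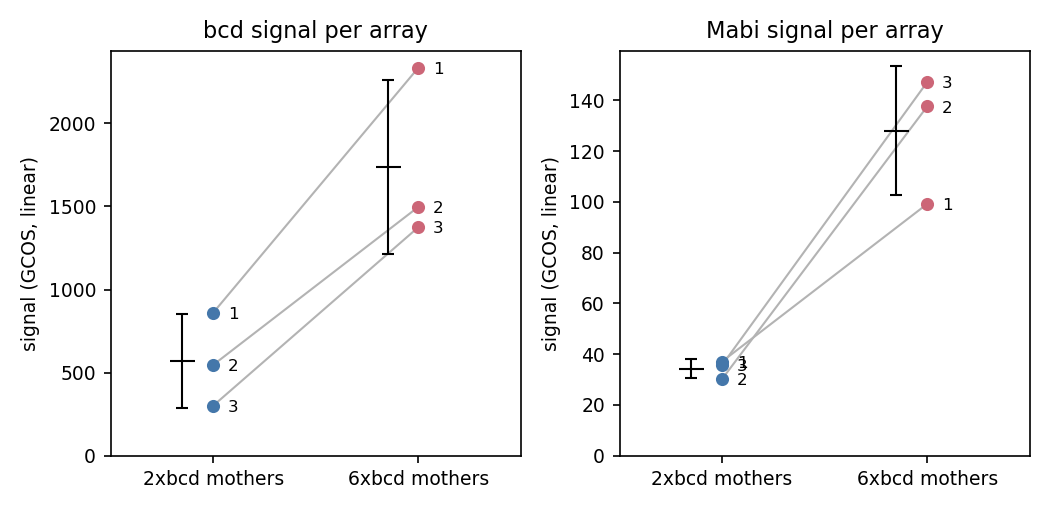
Signal of bcd (left) and Mabi (right) on each of the 6 arrays, on a linear axis in GCOS signal units. Grey lines join arrays of the same replicate number, written beside the points, and black bars give the mean and SD of 3 arrays: every 6xbcd point lies above every 2xbcd point for both genes.

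In all, 134 probe sets passed an adjusted p of 0.05 in limma, 76 higher and 58 lower in 6xbcd embryos. Of these, 45 differed by over 2-fold, 35 higher and 10 lower. All 134 had the same sign in 3 pairs, as did 39.0% of all tested probe sets. A paired fit favours such probe sets, so the shared sign adds no separate support. The count of 134 rests strongly on single pairs and on the variance prior. It was 17 without replicate 1, 10 without replicate 2, 270 without replicate 3 and 5 without the intensity trend. At an unadjusted p under 0.05 there were 1511 probe sets, against 506.85 from chance alone.

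Among named genes that rose, CG15601 on the X chromosome stood first. It read 365 ± 5.28 in 6xbcd and 5.77 ± 4.08 in 2xbcd embryos (SD, n = 3), where it was absent on all 3 arrays, and it was at least 15.6-fold higher (adjusted p = 0.00381). Sdic1, a member of a tandem family of sperm dynein intermediate chain genes on the X whose copies cannot be told apart here, was also absent in 2xbcd and at least 5.07-fold higher (adjusted p = 0.0136). CG34025 on 3L rose by a log2 change of 3.08 (SE 0.182, adjusted p = 0.00498) and CG2233 on the X by 2.15 (SE 0.206, adjusted p = 0.0207). Smvt, a sodium-dependent vitamin transporter, had a log2 change of 1.63, NaPi-T, a sodium and phosphate cotransporter, 1.63, and Slc45-1, a sugar transporter, 1.56. Also higher were sl, the phospholipase C gamma gene, at 1.68, CG9784 at 1.60, CG6125 at 1.55 and baz, the Par-3 gene of cell polarity, at 1.54. These 7 genes had adjusted p values from 0.00222 to 0.0459. Slc45-1 and CG6125 lost their call with an offset of 1 (adjusted p = 0.0509 and 0.0572), and NaPi-T and CG6125 without the filter (0.0573 and 0.0898). Of 23 named genes past the threshold other than bcd, 15 lost their call without replicate 1, 19 without replicate 2 and 20 without the intensity trend. For sl the authors' deposited table gave log2 ratios of 1.4, 0.4 and 0.3 in pairs 1, 2 and 3, where its signal changed by 1.62, 1.62 and 1.79.

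The named genes that fell the most were X-linked, except CG9449. The signal of pigs, which encodes a cytoskeletal linker protein, fell from 900 ± 94.3 in 2xbcd to 157 ± 26.0 in 6xbcd embryos (SD, n = 3), with a log2 change of -2.41 (SE 0.116, adjusted p = 0.00362). Pvf1, a ligand of the PDGF and VEGF receptor family, had a log2 change of -1.73, Ykt6, a SNARE of membrane fusion, -1.56, and Evi5, a Rab GTPase-activating protein, -1.32. Ldsdh1, a lipid droplet dehydrogenase, had -1.23, Gbeta5, a G protein beta subunit, -1.21, Acat1 -1.01, CG3566 -0.99, and fog, the secreted ligand of gastrulation movements, -0.99. CCT2, a chaperonin subunit, had -0.94, nonA, an RNA-binding protein gene, -0.90, and CG9449 on 3L -0.90. Adjusted p values of these 11 genes lay between 0.00498 and 0.0313. Without the replicate pairing, nonA (adjusted p = 0.153) and CG9449 (adjusted p = 0.0679) no longer passed. Other probe sets went apart from the called ones for Evi5, with log2 changes of 0.57, -0.42 and -0.11, and for nonA, with 0.07 and -0.03. The authors' deposited table gave CCT2 log2 ratios of 0, -0.3 and -0.3 and nonA -0.2, -0.3 and -0.4, and for Gbeta5 it gave -2.4, -2.2 and -2.5 but called no change in any pair.

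Called probe sets lay on the X chromosome more often than other tested probe sets. Of 1411 tested X-linked probe sets 54 were called (3.83%), 28 higher and 26 lower, against 54 of 7370 autosomal ones (0.733%), for an odds ratio of 5.39 (95% interval 3.61 to 8.05, Fisher's exact p = 1.79e-16, two-sided). Without the replicate pairing 46 of 75 called probe sets with a chromosome were X-linked, and the odds ratio was 8.53 (5.22 to 14.1). When autosomal probe sets were tested alone, limma called 0 of 7370 at an adjusted p of 0.05, and 969 had an unadjusted p under 0.05. The median log2 change was 0.01 on the X and 0.01 on the autosomes.

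**Figure D2:**
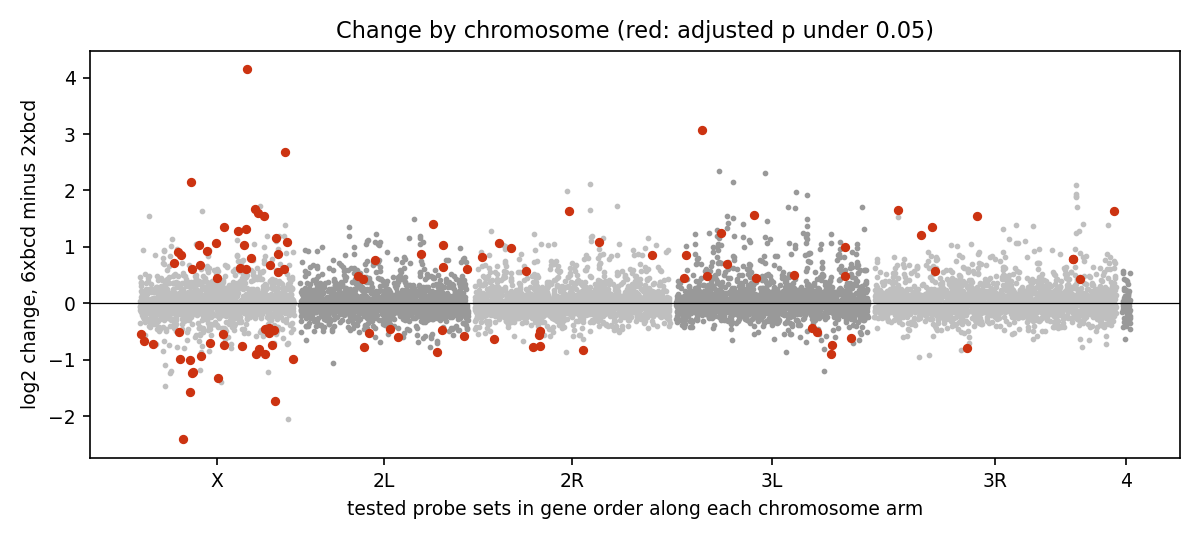
Log2 change (6xbcd minus 2xbcd) of each tested probe set with 1 gene symbol, in gene order along each chromosome arm. Red points passed an adjusted p of 0.05, 54 of them on the X, where they lie above and below 0.

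The authors' deposited table calls each pair of arrays by itself. An increase was called for 496, 732 and 1548 probe sets in pairs 1, 2 and 3, and a decrease for 678, 495 and 977. In all 3 pairs, the authors' deposited table called 144 increases and 103 decreases, where independent pairs would give 1.60 and 0.931 over all 18769 probe sets. Of these calls, 141 increases and 102 decreases lay among the 10137 tested probe sets, so the expected numbers are too low. Any lasting difference of stock or genotype would make the pairs agree too, so this agreement does not speak for the bcd dose. Of the probe sets called here, 61 of 76 higher and 43 of 58 lower ones were also called in all 3 pairs in the authors' deposited table. Of those with a chromosome, 33.3% of its increases and 45.6% of its decreases were X-linked, against 16.1% of tested probe sets.

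Gene lists fixed from the biology of the embryo were tested as groups with camera. The 30 lists with at least 3 measured members held 313 such members, counted per list, and fixed genes that were not measured were left untested. None of the 30 lists passed an adjusted p of 0.05. The lowest value, 0.0817, was shared by the germ cell and maternal RNAs, the trachea and the Notch targets. With an estimated correlation no list passed either, and the lowest adjusted p was 0.764. With fry, 0 lists passed for a change in 1 direction, while for a change in either direction 4 passed, namely the anterior gap and head gap genes (adjusted p = 0.0139), JAK-STAT and Wnt/Dpp ligands (0.0143), core apoptosis genes (0.0394) and maternal RNAs (0.0394). The last test does not compare a list with other genes. Some lists passed under other settings: the trachea list (lower) without the filter, without replicate 1 or 2 and without X-linked genes, the maternal list (higher) without the filter, the trend or replicate 2, the muscle list (lower) without replicate 3, the neural precursors (lower) without X-linked genes, and the blood cell and xenobiotic lists (higher) without replicate 1. For wound response, muscle, EGFR signalling, Hox genes, and JAK-STAT and Wnt/Dpp ligands, the median, the mean and the direction of the test differed in sign.

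Notch targets had 2 of 7 members past the gene-level threshold. E(spl)m5-HLH, a repressor of neural fate, rose by a log2 change of 0.78 (SE 0.0775, adjusted p = 0.0207) and E(spl)m4-BFM by 0.80 (SE 0.111, adjusted p = 0.0435). Without the replicate pairing their adjusted p values were 0.395 and 0.427, and with the main axis of the arrays as covariate 0.116 and 0.172. With that covariate their log2 changes were larger, at 1.07 and 1.08. Adjusted over the list alone 3 members rose, the other being E(spl)mdelta-HLH with 0.30. The list passed (higher) with quantile normalization (adjusted p = 0.0347), without the filter, without replicate 1 and without X-linked genes. With an estimated correlation its adjusted p was 0.764.

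Among patterning genes, none of the 15 anterior gap and head gap genes, 16 head and anterior brain genes, 6 pair-rule genes, 13 segment polarity genes, 4 head and thorax Hox genes or 10 posterior and hindgut genes passed. Their list tests gave adjusted p values of 0.749, 0.249, 0.814, 0.340, 0.889 and 0.306. The segment polarity, posterior and gap gene lists lay at percentiles 99.9, 99.1 and 98.7 of the main axis of the arrays, at the end of 2xbcd replicates 2 and 3. Optix, a head homeobox gene, had the smallest p of the head lists, with a log2 change of 0.42 (adjusted p = 0.096), and rose when adjusted over the list alone (limma adjusted p = 0.0337 and 0.0360). Others were kni at -0.18, toy at 0.17, gsb-n at -0.30, odd at -0.07, Antp at -0.13 and cad, the posterior homeobox gene, at -0.48. Abdominal Hox genes had no tested probe set of their own.

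Cell death and stress genes gave a mixed picture. Of 19 core apoptosis genes in the fixed list 14 were measured, and 0 of these passed the test over all probe sets (list adjusted p = 0.304). The genes rpr, hid, Drice, Decay and Diap1 were not among those measured, so nothing can be said of them. Adjusted over the list alone, Mabi rose and grim, an activator of apoptosis, fell with a log2 change of -0.81 (limma adjusted p = 0.0189). Mabi is a gene that the study's authors later named, so its rise within the list is no independent support. No member passed among JNK and TNF genes (egr -0.21, list adjusted p = 0.304), p53 and DNA damage genes (Corp -0.60, 0.662), autophagy genes (Atg4a -0.17, 0.441), wound genes (Ddc 0.77, 0.595), heat shock genes (Hsp26 0.49, 0.104) or immune genes (BomS2 0.88, 0.814). Of the genes fixed in these lists, in the same order, 10 of 13, 12 of 15, 19 of 20, 5 of 8, 6 of 16 and 6 of 24 were measured. Most heat shock and immune genes of the lists were thus not tested. Hsp26 passed when adjusted over the list alone (limma adjusted p = 0.044). The heat shock list passed without replicate 3 and when X-linked genes were left out, while its adjusted p was 0.764 with an estimated correlation. In the xenobiotic list (20 members, adjusted p = 0.145), the cytochrome P450 gene Cyp12d1-d fell by 0.78 on the log2 scale (adjusted p = 0.0224), while 17 of 20 members had positive changes, with a list median of 0.31. This list lay at percentile 0.08 of the main axis of the arrays, at the end opposite to 2xbcd replicates 2 and 3. Adjusted over the list alone 4 rose and 2 fell. Cyp12d1-d, on 2R, lost its call over all probe sets without the intensity trend and when autosomal probe sets were tested alone.

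Markers of tissues and stages were also tested. For blood cells (15 members, srp 0.26), neural precursors (14, nerfin-1 -0.29), neurons and glia (10, fne -0.37), muscle (17, Hand -0.45), trachea (7, kni -0.18), salivary gland (8, PH4alphaSG2 -0.25), endoderm and midgut (7, dpp -0.38) and late epidermis (13, TwdlT 0.90), 0 members passed. Their list adjusted p values were 0.108, 0.128, 0.304, 0.881, 0.0817, 0.441, 0.881 and 0.441. Hand, a heart and muscle regulator, fell when adjusted over the list alone (limma adjusted p = 0.0126), as did dpp, while srp rose in the endoderm list (adjusted p = 0.0447 for both). Maternal and germ cell RNAs had 11 of 13 positive changes and 0 past the threshold. They lay at percentile 0.87 of the main axis of the arrays, also opposite to 2xbcd replicates 2 and 3, while the muscle list lay at percentile 0, and the trachea (98.0) and neural precursors (100) at the end of those arrays. Adjusted over the list alone swa (0.72), png (1.54) and aub (0.43) rose and stau (-0.27) fell, each with a limma adjusted p of 0.0232. Both swa and png are X-linked, and png was dim in 2xbcd embryos, at 15.6 ± 12.5 (SD, n = 3). The early zygotic list (5 members, zld 0.20) had an adjusted p of 0.662.

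General pathways had no member past the threshold: ecdysone response (Hr39 -0.34, list adjusted p = 0.490), cell cycle (Mcm3 0.19, 0.417), EGFR signalling (spi -0.19, 0.749), JAK-STAT and Wnt/Dpp ligands (Stat92E 0.20, 0.814) and ribosomal proteins (RpL3 0.11, 0.749). Adjusted over the list alone, Hr39 fell (limma adjusted p = 0.0333) and in the JAK-STAT and Wnt/Dpp list Stat92E rose and dpp fell (limma adjusted p = 0.0343 for both). Of the sex and dosage compensation genes, with too few measured members for a list test, Sxl, the switch gene of sex determination, had a log2 change of -0.50 (adjusted p = 0.175) and msl-2 of 0.03.

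**Figure D3:**
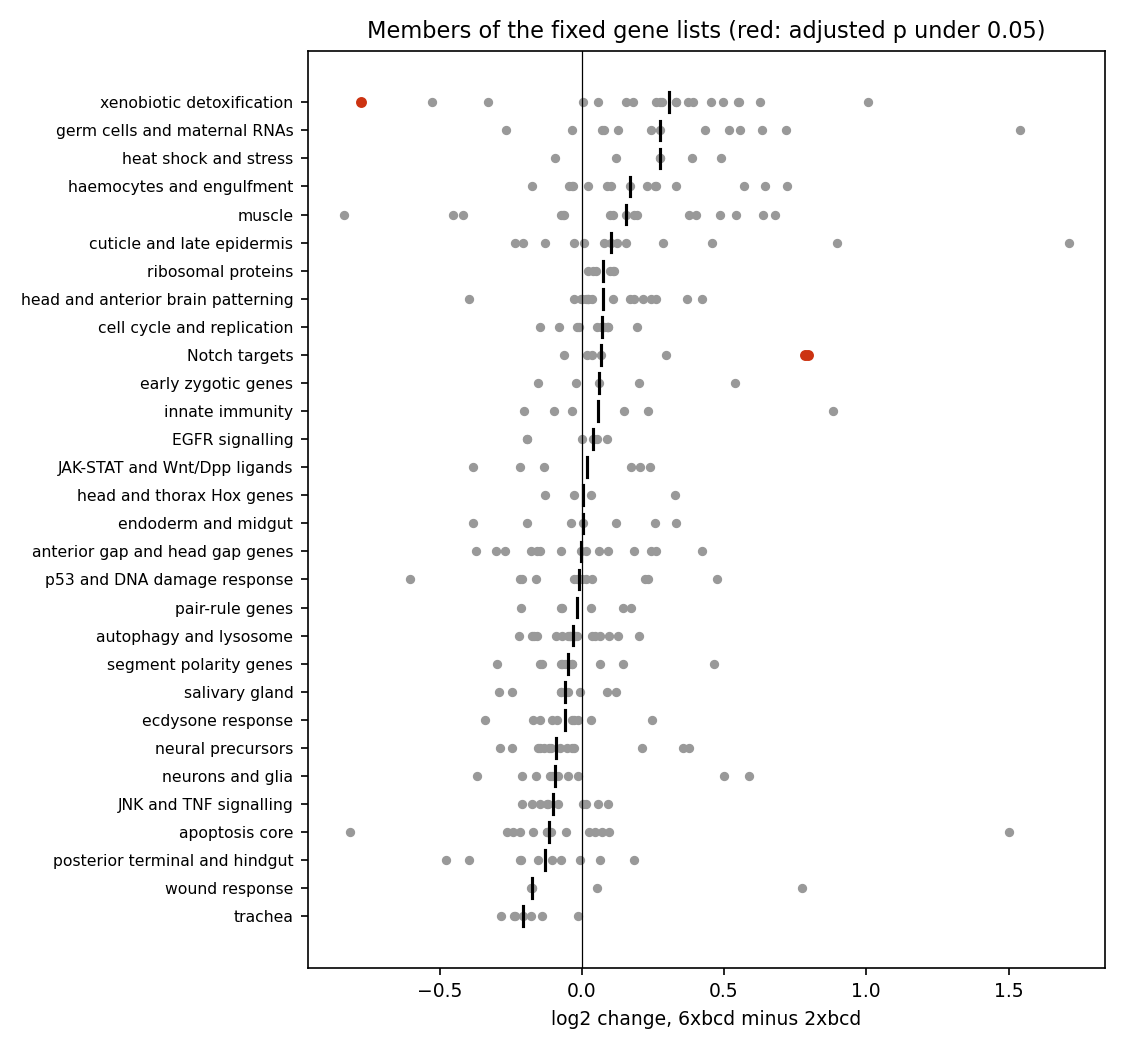
Log2 change (6xbcd minus 2xbcd) of each measured member of the 30 fixed gene lists, with black bars at list medians and lists ordered by median. Red points passed an adjusted p of 0.05: E(spl)m5-HLH and E(spl)m4-BFM among Notch targets and Cyp12d1-d in the xenobiotic list.

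The arrays also differed along a main axis that held 53.5% of the variance and on which the groups overlapped. The 6xbcd arrays lay at -21.4, 6.87 and -21.6 on it and the 2xbcd arrays at -22.3, 19.1 and 39.4, so that the highest values were those of 2xbcd replicates 2 and 3. The muscle, xenobiotic and maternal lists lay at the low end, at percentiles 0, 0.08 and 0.87 of 10000 matched random lists. The neural precursor and segment polarity lists lay at the high end, at percentiles 100 and 99.9. With this axis as a covariate in place of the block, chosen after seeing the data, limma called 97 probe sets, 83 of them among the 134, and the log2 change of bcd was 1.19 (adjusted p = 0.0839). Slc45-1 (log2 change 1.47, adjusted p = 0.0508), CG6125 (1.61, 0.0539), nonA (-0.88, 0.234) and CG9449 (-0.97, 0.0666) also lost their call. So did E(spl)m5-HLH and E(spl)m4-BFM, though their log2 changes of 1.07 and 1.08 were larger than with the block.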

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

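Both tests in this part were chosen after the result was seen. A second bcd probe set, with an absent call on all 6 arrays and so outside the tested set, drew attention as a signal in data the comparison did not use. It read 129 ± 16.6 in 6xbcd and 12.2 ± 8.90 in 2xbcd embryos (SD, n = 3), and no fold is given because it was not above background in either group. The higher signal of the tested bcd probe set may reflect a larger maternal load, a hypothesis that the design names. It was not tested apart from the stock or from the embryos' own genotype. Before the data were examined, maternal bcd RNA was expected to be largely degraded by these stages. A rise as large as that of bcd is argued against for most of the list of germ cell and maternal RNAs. Its median log2 change was 0.275 (95% bootstrap interval 0.0792 to 0.557), below 1.35, the value for bcd less 2 standard errors. The bootstrap drew genes and not arrays, so the interval leaves out the spread between arrays. The bound of 1.35 holds for the fit with the pairs as a block. With the main axis of the arrays as covariate the log2 change of bcd was itself 1.19. However, png lay above 1.35, at 1.54, and 11 of 13 members were positive. The gene png is X-linked and was dim in 2xbcd embryos, at 15.6 ± 12.5 (SD, n = 3). The list also holds germ cell genes, so its median need not measure remaining maternal RNA, and more of it stays open as a cause. Against an artefact of 1 probe set go the increase calls of the second probe set in all 3 pairs of the authors' deposited table. So does its limma adjusted p of 0.0467 without the filter. The artefact still stays open, because that probe set had a present call on 0 of 6 arrays, so that its signal was not told from background.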

How the results depend on the processing

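The alternatives with the main axis, autosomes alone and X-linked genes left out were chosen after seeing the data, and the cause of a change was not tested unless stated. Without the replicate block 97 probe sets were called, 84 of them among the 134, and bcd (log2 change 1.66, adjusted p = 0.118), nonA, CG9449, Bhmt and both E(spl) genes lost their call, while Mabi gained one. With an offset of 1 Slc45-1, CG6125 and pug lost theirs, and without the filter NaPi-T, CG6125 and pug. The threshold of 0.1 gave 247 probe sets (130 higher, 117 lower), a present call on all 6 arrays 94 lower ones, and the fit without the trend 5 (4 higher, 1 lower), 3 named genes and bcd at 1.66 with an adjusted p of 0.140. Without 1 pair, counts ran from 10 to 270 (7 to 150 higher, 3 to 120 lower), named genes from 4 to 25 and the log2 change of bcd from 1.43 to 1.78. Leaving out single arrays, with no block, gave 38 (27 higher, 11 lower), 15 named genes and bcd 1.43 without 6xbcd replicate 1; 23 (12 higher, 11 lower), 9 named genes and bcd 1.75 without 6xbcd replicate 2. It gave 32 (16 higher, 16 lower), 12 named genes and bcd 1.81 without 6xbcd replicate 3; 88 (62 higher, 26 lower), 18 named genes and bcd 2.01 without 2xbcd replicate 1. The last of these fits gave 25 (13 higher, 12 lower), 11 named genes and bcd 1.69 without 2xbcd replicate 2; 36 (21 higher, 15 lower), 12 named genes and bcd 1.28 without 2xbcd replicate 3. Autosomal probe sets alone gave 0 (0 higher, 0 lower), with bcd at 1.66 and an adjusted p of 0.0730. The axis as covariate gave bcd 1.19 (adjusted p = 0.0839). Over all alternatives the adjusted p of bcd ran from 2.51e-05 to 0.374. Gene lists past the threshold numbered 0 in the reported test, 1 with quantile normalization, 3 without the filter, 1 without the trend, 2 to 4 without 1 pair and 4 without X-linked genes. Dim probe sets are limited by their signal over background. Of 2813 values of single genes, 2544 kept direction and side of the threshold, 197 lost a call, 16 gained one and 56 changed sign. Sign changes were in list members that had no call, here by log2 change. Over the fits without 1 pair: Dfd -0.0925 to 0.0240, Drs -0.0486 to 0.511, msl-2 -0.156 to 0.186, RpL3 -0.0517 to 0.286, RpLP1 -0.0578 to 0.259, RpL32 -0.0591 to 0.214, RpLP2 -0.143 to 0.216, Scr -0.0628 to 0.101, Sry-alpha -0.0659 to 0.256, PGRP-LB -0.650 to 0.145, aos -0.0222 to 0.119, E(spl)m3-HLH -0.133 to 0.0115, Ama -0.0917 to 0.0369, Mlp60A -0.00947 to 1.12, EcR -0.271 to 0.00801, Hr3 -0.329 to 0.00261, Tep4 -0.0915 to 0.0541. With quantile normalization: Sry-alpha -0.0369. Without 6xbcd replicate 1: opa 0.0344, Drs -0.0393, RpL3 -0.0446, RpLP1 -0.0337, RpL32 -0.0427, RpLP2 -0.111. Without 6xbcd replicate 2: Dfd 0.00822, nrv2 0.0940, Sry-alpha -0.103, EcR 0.0964, PGRP-LB 0.0659. Without 6xbcd replicate 3: Ama 0.0936, ptc -0.0384, Scr -0.0491, serp 0.144, Hr3 0.0158, Tep4 0.0461, aos -0.0200. Without 2xbcd replicate 1: ptc -0.0762, Scr -0.0102, Dfd 0.0373, PGRP-LB 0.0613, aos -0.0151, msl-2 -0.155. Without 2xbcd replicate 2: Ama 0.0342, Scr -0.0345, aos -0.0173. Without 2xbcd replicate 3: opa 0.0178, PH4alphaSG1 0.00466, nrv2 0.0736, Gasp -0.104, EcR 0.191. With the axis as covariate: opa 0.0898, Mlp60A -0.144, vvl 0.00521, ftz-f1 -0.0554, E(spl)m3-HLH 0.00519.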

Other observations

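Genes outside the fixed lists also rose in 6xbcd embryos; those named here were chosen after their values were seen. PPO1 and PPO2, which encode prophenoloxidases of crystal cells, the melanising blood cells, rose together. PPO1 read 2539 ± 455 against 1172 ± 55.9 (SD, n = 3), a log2 change of 1.09 (SE 0.117, limma adjusted p = 0.0221), and PPO2 4342 ± 679 against 2176 ± 133, a log2 change of 0.98 (SE 0.108, adjusted p = 0.0224). Both were higher in 3 of 3 pairs. Without replicate 1 or 2 their adjusted p values were 0.124 and 0.097, and 0.125 and 0.1997. Both autosomal genes also lost their call without the intensity trend and when autosomal probe sets were tested alone. In each of these fits 0 autosomal probe sets were called.

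Bhmt, Shmt and pug, which encode enzymes of one-carbon metabolism, were also picked after their values were seen. Bhmt rose by a log2 change of 1.03 (SE 0.0915, adjusted p = 0.0168), Shmt, on the X, by 0.91 (SE 0.0923, adjusted p = 0.0207) and pug by 0.58 (SE 0.0842, adjusted p = 0.0491), each higher in 3 of 3 pairs. Without the replicate pairing the adjusted p of Bhmt was 0.0530. The call of pug was lost with an offset of 1 (adjusted p = 0.0513), without the filter (0.0609) and with the main axis of the arrays as covariate (0.0742). Without replicate 1 or 2, or without the intensity trend, all 3 genes lost their call. Other enzymes of this pathway were not counted and no enrichment was tested.

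Of the tests of the X chromosome, that of single probe sets was written before its result was seen, and the others after. Their intervals take probe sets as units and do not cover the spread between embryo batches. Among the calls, which lay on the X with an odds ratio of 5.39, a shift of the whole X is argued against by the difference of medians of -0.0073 (95% bootstrap interval -0.0243 to 0.00598). Variants under a few probes could account for part of the calls: the authors' mean probe-pair ratio was under 50% of the change of the signals for 13 X-linked and 1 autosomal call, an odds ratio of 16.5 (95% interval 2.30 to 727, Fisher's exact p = 0.000903). The authors' change calls in all 3 pairs also favoured the X, with an odds ratio of 3.37 (2.47 to 4.57). These calls cannot decide whether variants are the whole cause, because they were made on the same probes. Small ratios were called too, such as decreases at -0.3 and -0.4 for nonA. Other probe sets of the called genes had a median signed log2 change of 0.077 (-0.0509 to 0.331). By the bound set beforehand, this median would have counted for variants under single probe sets. The interval is wide and some genes gave several of these probe sets, so such variants stay open. A different X chromosome in the bcd+t8 stock cannot be told apart from the bcd dose, since stock and dose split the arrays alike; the share with an unadjusted p under 0.05 and a log2 change over 0.5 was at least 1.95 times as high on the X as on the autosomes, in both directions.

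Of the tests of the main axis of the arrays, that of developmental age by the late epidermis list was written before its result was seen, and those by detection, muscle and neural precursors after. The late epidermis list lay at percentile 6.08 of random lists, within the central 95%, which by the bound set beforehand would have counted against age. That bound was a poor choice, because 13 of 24 late epidermis genes were measured at these stages, and the muscle and neural precursor lists lay at percentiles 0 and 100; age thus stays open. Detection stays open too: the axis and the number of present calls correlated over 6 arrays at Pearson's r = -0.780 (exact permutation p = 0.0708) and Spearman's rho = -0.886 (exact permutation p = 0.0333), as the 1 relation computed, and at -0.319 and -0.6 without the 2 arrays farthest from the median, on which it rests.

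The tests on other splits were written before the result was seen. The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 134 probe sets, 3 splits gave at least as many, and the highest other gave 259. Those 2 other splits part only the third pair and give the same contrast under the block. That contrast is 6xbcd against 2xbcd in this pair alone. The splits that part only pair 1 or only pair 2 carry the same contrast of groups and gave 0 probe sets. The count of 259 is thus particular to pair 3, whose arrays lay at -21.6 (6xbcd) and 39.4 (2xbcd) on the main axis. In this pair the bcd dose and a structure of the arrays cannot be told apart. Without the block, the split of 6xbcd replicates 1 and 3 with 2xbcd replicate 1 gave 163 against 97 for the real split, and all others gave 0. The count of 163, from a split that mixes the groups, points to a structure of the arrays apart from the bcd dose. Of the splits that part all 3 pairs, the others gave 0 probe sets. For gene lists the real split gave 0, the highest other 3, and 10 of 10 splits gave at least as many.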
